A study of Mus musculus with 6 samples.

How the data were processed

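Gene expression was measured in CD4 T cells from the spleen and lymph nodes of C57BL/6 mice. The series description gives 3 mice lacking miR-155 (KO) and 3 wild type (WT), with 1 array per mouse. Per the labels' protocols, the cells were taken out with CD4 magnetic beads and cultured for 3 days with antibodies to CD3 and CD28 at 1 µg/mL and interleukin 2 at 20 U/mL, and biotin-labelled RNA was then hybridised to an Affymetrix array. Because the series description assigns each array to its own mouse, the 3 arrays of a genotype were treated as biological replicates. Both replicate 3 arrays carried Xist and Y-linked transcripts together (described below), so 1 mouse per array is not certain for them.

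The deposited log2 values were made by the authors with RMA and the affy package, per the submitters' processing notes, whose versions are not given in the sources used here. RMA subtracts a background estimate, brings the arrays to a common distribution and summarises the probes of each probe set on the log2 scale. Such summaries compress differences near the background, so a difference of a dim gene is likely to be understated. The table held 22690 probe sets on each of 6 arrays, of which 64 were controls, and the array medians lay between 6.45 and 6.49. All 6 columns were mapped to a sample. No detection calls were used here, so no value could be marked as above or below background, and the number of arrays limits the precision.

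Probe sets were named through GEO's annotation of the platform. In it, 20393 probe sets had 1 gene symbol, 691 had several and 1606 had none in the table used. Of the resulting 12394 genes, 12370 were found by their gene number in a RefSeq gene table of assembly GRCm38.p6 and 24 were not, and no symbol had to be updated. That table served only for names and for neighbouring genes. For each gene the probe set with the highest mean over all 6 arrays was kept. The 25% of genes with the lowest mean were left out, which removed 3099 genes and left 9295, the dimmest with a mean of 4.72. The 2246 probe sets without a single gene were tested apart and are not named.

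KO and WT were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, two-sided, Benjamini-Hochberg adjustment over the 9295 genes, adjusted p under 0.05). All differences are KO minus WT on the log2 scale. In addition, 34 gene lists and cell type marker lists were fixed, of which 30 had at least 3 tested members and were tested with camera, limma's competitive list test, at a preset correlation between genes of 0.01, with the adjustment running over the 30 lists. A count adjusted over the list alone is the number of members with adjusted p under 0.05 when only that list's genes are adjusted. Differences of single values were also put to an exact two-sided permutation test, which for 3 against 3 arrays cannot give a p below 0.1.

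The lists were reported miR-155 targets, Th1, Th2, Th17, Treg, Tfh, naive and memory T cells, T cell activation and costimulation, type I and type II interferon response, cytokine signalling regulators, cell cycle, glycolysis, HIF response, sterol synthesis, apoptosis, cytotoxic granule and effector genes, chemokines and their receptors, NF-kappa B pathway, heat shock and stress, immediate early genes, microRNA pathway, genes near Mir155 and sex-linked genes, with markers of CD4 T cells, CD8 T cells, B cells, NK cells, gamma delta T cells, macrophages and monocytes, dendritic cells, neutrophils, erythroid cells and platelets. The genes named were every probe set of the targeted gene, then per direction the 12 genes with the largest difference among those past the test and with all KO arrays on one side of all WT arrays. Where fewer than 12 passed, those with the next smallest p filled up to 6. From each list up to 4 members past the test were named, or the 2 with the smallest p where none passed, and every member of the target list past the test. This gave 67 genes, of which 32 had several probe sets and 2, Ikzf4 and Kdm5d, had a probe set of opposite sign. The lists, the naming rule, the tests and most alternatives were chosen before the data were examined.

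The alternatives were the replicate number as a block, each array left out in turn, median centring, a second quantile normalization, no filter, a filter at 50%, the mean of all probe sets, eBayes with trend and robust settings, array weights (statmod 1.5.0), a minimum fold of 1.5, an adjusted p under 0.1, a plain test without moderation, an estimated correlation per list and fry, limma's rotation test. Leaving out the genes of the sex chromosomes, and leaving 6 members out of the target list, were added after the data had been seen. A planned test of miR-155 seed matches was not run, because no 3' UTR sequences were used here.

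The code was tested on simulated data with the means and spreads of the 9295 genes, for the comparison of KO with WT. With 200 genes changed by 1, 2 or 3 log2 units, limma called 60.0%, 88.5% and 97.5% of them, and with no change it called 0 genes. Camera called 50 of 50 lists of 33 genes shifted by 0.3 and 3 of 200 lists that were not shifted. The simulated genes varied independently, which real genes do not. The adjusted threshold also depends on how many genes change, so these percentages are not the power in the real data. Figures were drawn with matplotlib 3.10.9.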

Results

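Transcript levels were compared between 3 arrays of activated CD4 T cells from miR-155 knockout (KO) mice and 3 from wild-type (WT) mice, after 3 days of culture. MiR-155 is a microRNA made from the transcript of its host gene, Mir155hg, and is induced when T cells are activated. The question was how transcripts, among them those reported as targets of miR-155, differ in its absence. The first principal component held 61.9% of the variance between arrays and did not separate the genotypes. KO replicates 1 and 3 and WT replicate 3 had scores of -41.3, -14.6 and -7.36, and KO replicate 2 and WT replicates 1 and 2 had scores of 13.4, 26.1 and 23.8. The lowest scores were of KO arrays and the highest of WT arrays, so the component was not unrelated to genotype.

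The targeted locus was examined first. Mir155hg (1 probe set on the array) measured 3.51, 3.89 and 4.45 on the KO arrays and 7.69, 6.59 and 8.21 on the WT arrays, in log2 units. The means were 3.95 ± 0.47 (SD, n = 3) and 7.50 ± 0.83 (SD, n = 3), a log2 difference of -3.55 ± 0.44 (SE), or 11.7-fold lower in KO, and every array lay on the side its genotype label gives. The KO values lay below 4.72, the mean of the dimmest gene tested, so the fold may be understated. The gap exceeded the spread between replicates, but the limma adjusted p was 0.545, and the exact permutation p was 0.1, the smallest that 3 against 3 arrays can give. The sources used here do not say which part of the locus was deleted, and a probe set outside that part would not check the labels.

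Beyond Mir155hg, the genes with the smallest p were Plac8, Il21, Serpinb1a, Pmaip1, Moxd1 and Gzma on the higher side and Scd1, Magee1, Lipg, Dusp14 and Pter on the lower side, none of them past the test over all genes. Gzma, which encodes the protease granzyme A of cytotoxic granules, measured 13.2 ± 0.15 (SD, n = 3) in KO and 10.1 ± 1.14 (SD, n = 3) in WT, a log2 difference of 3.08. Il21, a cytokine that acts on B and T cells, measured 10.5 ± 0.16 in KO against 8.24 ± 0.64 in WT (SD, n = 3). Plac8 had a log2 difference of 2.11 ± 0.24 (SE), Moxd1 of 1.49, the protease inhibitor gene Serpinb1a of 1.43 and Pmaip1, which encodes the pro-apoptotic protein Noxa, of 1.26. Moxd1 had a WT mean of 4.56, below that of the dimmest gene tested (4.72), so its difference may be understated. On the lower side, Pter differed by -1.25, Scd1, the stearoyl-CoA desaturase, by -1.22, Dusp14 by -0.86, the endothelial lipase gene Lipg by -0.84 and Magee1 by -0.70. In all 11 genes the 3 KO arrays lay on one side of the 3 WT arrays. Of the weaker probe sets of Lipg, 1 differed by -0.80 and 1 by -0.000453, and those of Serpinb1a and Pter differed by 0.33 and -0.47.

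Over the 9295 genes, 0 had a limma adjusted p under 0.05, the smallest being 0.545. At an unadjusted p under 0.05 limma gave 691 genes, 332 higher and 359 lower in KO, where 464.75 would pass with no effect, and the plain test without moderation gave 0 adjusted and 554 unadjusted. In 1188 genes, or 12.8%, the KO and WT arrays did not overlap, against 10% by chance. A log2 difference of at least 1 was seen in 107 genes, 81 higher and 26 lower in KO. Of the 2246 probe sets without a single gene, limma gave 0 adjusted and 138 unadjusted. The unadjusted count ranged from 276 without WT replicate 1 to 1540 without KO replicate 2, so it rests on single arrays.

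**Figure D1:**
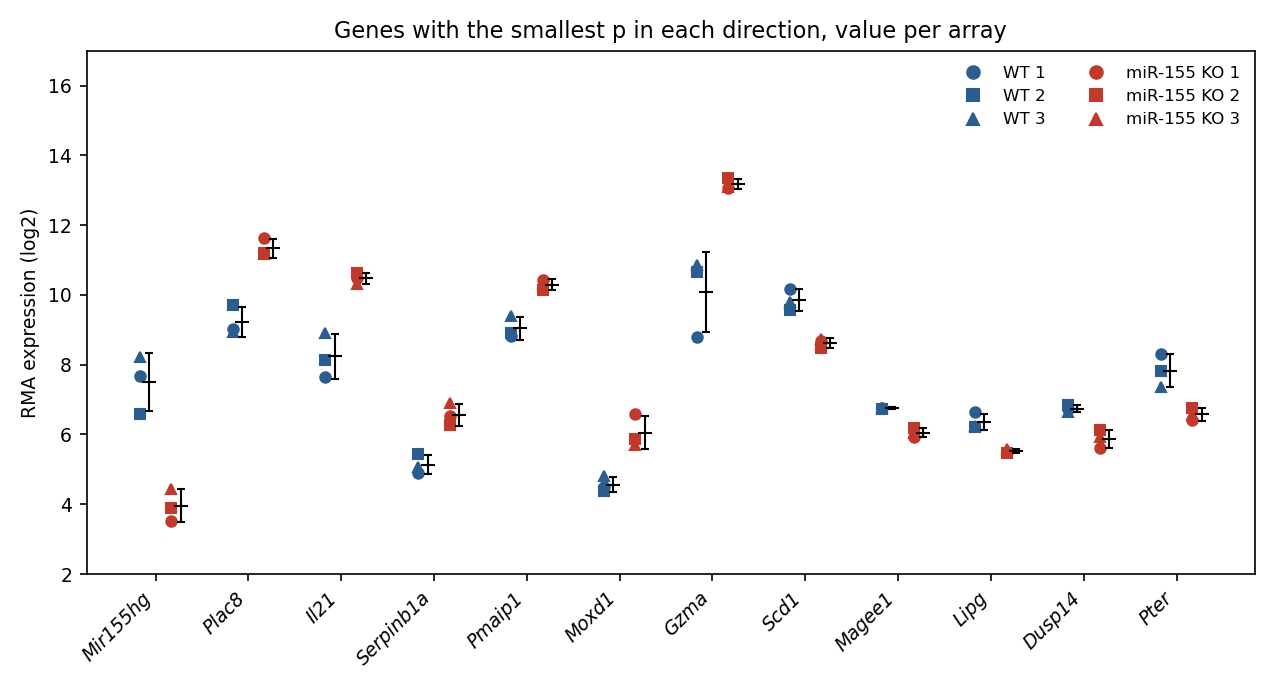
RMA expression (log2) of Mir155hg and of the 6 higher and 5 lower genes with the smallest p, per array, for WT (blue) and miR-155 KO (red), with the mean and SD of 3 arrays in black. Mir155hg lies at 3.51 to 4.45 in KO and 6.59 to 8.21 in WT, and in Gzma the WT replicate 1 array, at 8.78, lies below the others.

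Transcripts reported as direct targets of miR-155 rose as a group in its absence. Of 33 tested targets, 27 were higher and 6 lower in KO, with a mean log2 shift of 0.30 and a median of 0.21, or 1.23-fold (camera adjusted p = 5.07e-06). That p took the preset correlation of 0.01 between genes. The correlation estimated for these genes was 0.087, and with it the camera adjusted p was 0.528. Some splits of the arrays that do not follow genotype also gave this list a small unadjusted camera p, down to 1.20e-05 (given at the end). Mean scores of the list were 0.28, 0.05 and 0.12 on the KO arrays and -0.26, -0.12 and -0.06 on the WT arrays, relative to the mean of all 6 arrays (exact permutation p = 0.1). No target passed over all genes tested, while 4 passed when adjusted over the list alone. These were Hif1a, an oxygen-responsive transcription factor, at 0.49 ± 0.12 (SE), Peli1, a ubiquitin ligase, at 0.91 ± 0.22, Tab2, an adaptor in NF-kappa B signalling, at 0.63 ± 0.15, and Rreb1 at 0.56 ± 0.14, each with a limma adjusted p of 0.044 within the list.

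Beside these, Jarid2 (log2 difference 1.05), the interferon gamma receptor gene Ifngr1 (0.89), Cebpb (0.79, and 0.46 without KO replicate 1), Bach1 (0.74, and 0.49 without that array) and Tspan14 (0.65) had an unadjusted limma p under 0.05, and no target had one on the lower side. Socs1, a brake on cytokine signalling, measured 9.45 ± 0.42 in KO and 9.50 ± 0.20 in WT (SD, n = 3), a difference within the spread. Rreb1, Jarid2, Ifngr1, Cebpb, Tspan14 and Socs1 fall outside the naming rule and were chosen after their values were seen. Some of these targets may first have been reported from these very arrays, so the direction of the list is not independent evidence. Without Bach1, which lies near Mir155, and without Peli1, Rreb1, Tspan14, Jade1 and Sertad2, which could have been, the shift was 0.24 (camera adjusted p = 0.00202), a choice made after the data had been seen. Among the targets past adjusted over the list alone, Peli1 and Rreb1 may stem from these arrays, so those calls are not independent evidence either.

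**Figure D2:**
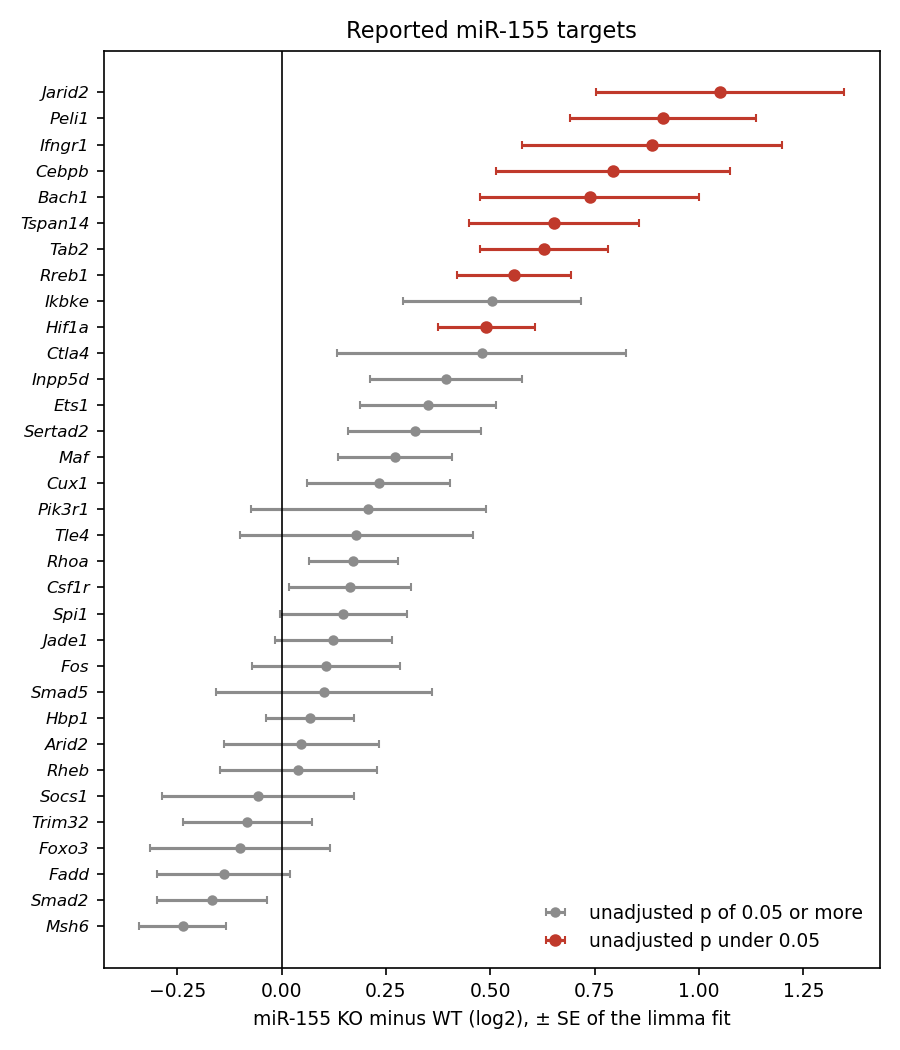
Log2 difference, KO minus WT, of each of 33 tested reported miR-155 targets, with bars for the SE of the limma fit over 3 arrays per group and red for unadjusted p under 0.05. In all, 27 lie above 0 and 6 below, and the 9 in red are all above 0.

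Cell cycle genes fell as a group in KO. All 27 tested members were lower, with a mean log2 shift of -0.59 and a median of -0.62 (camera adjusted p = 1.05e-09). That p took the preset correlation of 0.01 between genes. The correlation estimated for these genes was 0.67, and with it the camera adjusted p was 0.530. The small p thus rests on the preset correlation. The members included the mitotic kinase genes Bub1, at -0.37 ± 0.11 (SE), and Aurkb, at -0.49 ± 0.17 (-0.32 without KO replicate 1). No member passed over all genes or adjusted over the list alone, and 5 had an unadjusted limma p under 0.05. KO replicate 1 stood apart with a list score of -0.88, against 0.12 and -0.11 on the other KO arrays and 0.37, 0.33 and 0.18 on the WT arrays. Without it the shift was -0.29 (camera adjusted p = 3.00e-07 at the preset correlation).

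Sterol synthesis genes also fell, 14 of 16 being lower, with a mean shift of -0.24 (camera adjusted p = 0.0044, and adjusted p = 0.562 with an estimated correlation). Dhcr7, the last enzyme of cholesterol synthesis, differed by -0.46 ± 0.18 (SE) and Fdps, the farnesyl diphosphate synthase, by -0.36 ± 0.16 (a weaker probe set by -0.016), and 0 members passed adjusted over the list alone. KO replicate 1 again stood apart, at -0.41 against 0.02 and 0.02 on the other KO arrays. The call ended without KO replicate 1 (shift -0.10, Dhcr7 -0.26 and Fdps -0.22, camera adjusted p = 0.0913) and without WT replicate 3 (shift -0.21, camera adjusted p = 0.0804).

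Genes of cytokine and NF-kappa B signalling had higher list means in KO. Of 17 NF-kappa B genes 14 were higher, with a mean shift of 0.29 (camera adjusted p = 0.00527, and adjusted p = 0.528 with an estimated correlation). Tab2 at 0.63 and Bcl3, an atypical inhibitor protein of the pathway, at 0.88 (0.56 without WT replicate 1) had the smallest p. Of 16 cytokine signalling regulators 12 were higher, with a mean shift of 0.26 (camera adjusted p = 0.00962, and adjusted p = 0.530 with an estimated correlation). The regulators' list scores overlapped between genotypes (exact permutation p = 0.2). They were 0.27, 0.01 and 0.12 on the KO arrays and -0.32, -0.16 and 0.08 on the WT arrays. Pim1, a kinase gene, was at 0.59 and Socs3, a feedback inhibitor, at 1.26. In both lists 0 members passed adjusted over the list alone. Tab2 and Ikbke are shared between the targets and the NF-kappa B list, and Inpp5d and Socs1 between the targets and the regulators. Both calls ended without KO replicate 1, with shifts of 0.18 and 0.20 (camera adjusted p = 0.0566 and 0.0775), and the regulators' shift was 0.17 without WT replicate 1.

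Immediate early genes rose by a mean of 0.33, 11 of 13 being higher (camera adjusted p = 0.019, and adjusted p = 0.668 with an estimated correlation). Jun, a subunit of the AP-1 transcription factor, was at 1.06 ± 0.26 (SE) and Ier3 at 0.80 ± 0.28, with 0 members past adjusted over the list alone. WT replicate 1 stood apart with a list score of -0.54, against -0.02 and 0.07 on the other WT arrays. The call ended without it (shift 0.14, camera adjusted p = 0.105), and also without KO replicate 2 or 3 (shifts 0.36 and 0.27, camera adjusted p = 0.0582 and 0.0604).

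Among T helper programmes, the Th17 list rose by a mean of 0.45, 8 of 11 being higher (camera adjusted p = 0.019, and adjusted p = 0.528 with an estimated correlation). Il21 was the 1 member past adjusted over the list alone, Batf, a transcription factor, was at 0.72 and the interleukin 1 receptor gene Il1r1 at 0.44. The cytokine gene Il17a, which gives the subset its name, measured 4.83 in KO and 4.93 in WT, close to the mean of the dimmest gene tested (4.72), so no difference can be read from it (a gene outside the naming rule, chosen after its values were seen). The call ended without KO replicate 1 or 2 (shifts 0.37 and 0.50, camera adjusted p = 0.0775 and 0.0582) and with the replicate number, whose sex markers match across genotypes, as a block (shift 0.45, camera adjusted p = 0.0661).

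The cytotoxic list rose by a mean of 0.54 and a median of 0.23, 6 of 9 being higher (camera adjusted p = 0.0297, and adjusted p = 0.528 with an estimated correlation). Adjusted over the list alone 3 members passed, in opposite directions. Gzma and Prf1, the perforin gene, were higher, at 3.08 and 1.27, and Fasl, a death ligand, was lower, at -1.33. A weaker Prf1 probe set differed by 0.06. The call ended without KO replicate 1, KO replicate 2 or WT replicate 3 (shifts 0.50, 0.57 and 0.62, camera adjusted p = 0.089, 0.0582 and 0.0757) and under a further quantile normalization or another filter. In all, 8 of 30 lists passed camera, 6 higher and 2 lower, and 3 passed without KO replicate 1. With array weights the calls of 6 of these lists ended, sterol synthesis at a shift of -0.13 (camera adjusted p = 0.144), NF-kappa B at 0.24 (0.162), cytokine regulators at 0.27 (0.0996), immediate early genes at 0.32 (0.14), Th17 at 0.44 (0.162) and the cytotoxic list at 0.48 (0.183). With an estimated correlation 0 passed adjusted and 1, the reported targets, unadjusted (camera p = 0.0393). Splits of the arrays that do not follow genotype gave up to 9 lists past camera (given at the end). A count of 8 lists is thus not particular to the genotypes.

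**Figure D3:**
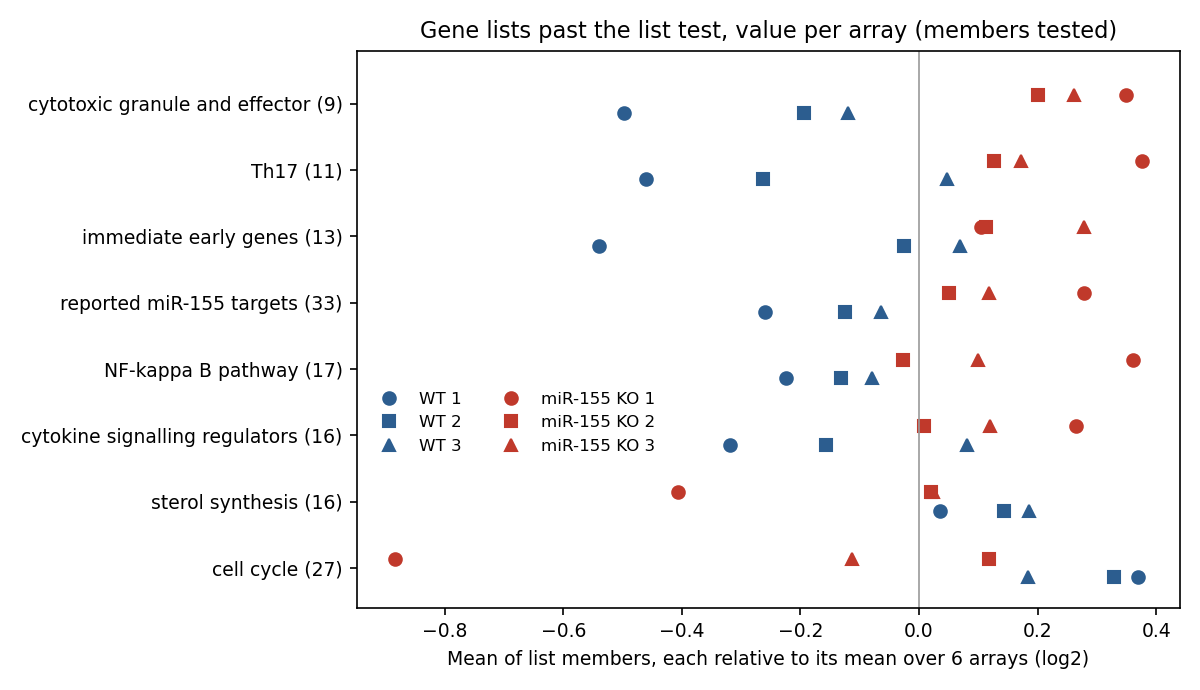
Mean of the members of each of the 8 lists past the camera test, per array, each gene relative to its mean over the 6 arrays (log2), for WT (blue) and miR-155 KO (red), with the number of members tested in brackets. KO replicate 1 lies at -0.88 for cell cycle genes and WT replicate 1 at -0.54 for immediate early genes.

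The other T cell lists did not pass with all 6 arrays. A range in brackets, here and for the pathway and marker lists, spans the values with 1 array left out, and is given for each of these lists and each gene that moved by over 1.5 times. Th2 genes shifted by 0.26 (0.015 to 0.42, camera adjusted p = 0.0757), with Ecm1 at 1.90 and Nfil3 at 0.73. They passed without KO replicate 2, KO replicate 3 or WT replicate 1 (camera adjusted p = 0.0367, 0.0173 and 0.022). Th1 genes shifted by 0.19 (0.13 to 0.28, camera adjusted p = 0.185), with Il12rb2 at 0.60 and Fasl at -1.33. Treg genes shifted by 0.14 (0.064 to 0.22, camera adjusted p = 0.341), with Itgae at 0.90 and Ikzf4 at -0.32 (-0.45 to -0.20). Naive and memory genes shifted by 0.20 (0.082 to 0.30, camera adjusted p = 0.19), with Bach2 at 0.36 and Il7r, the interleukin 7 receptor gene, at 1.34. The Tfh list had a mean of 0.17 (0.10 to 0.24) but a median of -0.13 (camera adjusted p = 0.865), with Il21 at 2.24, past adjusted over the list alone, and Bcl6, the transcription factor of these cells, at 1.59 (0.93 to 1.94). Bcl6 was at 5.65 on WT replicate 1 against 7.69 and 7.63 on the other WT arrays, the difference without that array was 0.93, and a weaker probe set differed by 0.61. T cell activation genes had a mean of -0.04 (-0.059 to -0.014) and a median of 0.04 (camera adjusted p = 0.921), with Cd44 at -0.57 (-0.67 to -0.37) and Batf at 0.72. Chemokine genes shifted by 0.33 (0.23 to 0.46, camera adjusted p = 0.086) and passed without WT replicate 1 (camera adjusted p = 0.0318). Of these, Ccr1, at 1.05, passed adjusted over the list alone and had a weaker probe set at 0.15, and Ccl1 was at -1.06. The WT mean of Ccr1 was 4.47, below that of the dimmest gene tested (4.72), so its difference may be understated.

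Among pathway lists, HIF response genes shifted by 0.39 (-0.15 to 0.78, camera adjusted p = 0.0634), with Vegfa at 0.65 (0.26 to 0.86) and Ddit4 at 0.52 (0.19 to 0.69). KO replicate 1 had a list score of 1.28 there, against -0.58 to -0.02 on the other arrays, and without it the shift was -0.15. The list passed without KO replicate 2 (0.78), KO replicate 3 (0.55) or WT replicate 2 (0.39), with camera adjusted p = 0.00251, 0.00384 and 0.0411. The microRNA pathway shifted by 0.20 (0.16 to 0.23, camera adjusted p = 0.0918), with Tarbp2 at 0.52 and Tnrc6b at 0.57. Type II interferon genes shifted by -0.21 (-0.38 to -0.10, camera adjusted p = 0.118), with Psmb9 at -0.39 and Iigp1 at -0.97 (-1.40 to -0.44). This list passed without KO replicate 2 or WT replicate 3 (camera adjusted p = 0.0332 and 0.00328) and with array weights (-0.42, camera adjusted p = 0.0132). Type I genes shifted by 0.02 (-0.16 to 0.20, camera adjusted p = 0.657), with Ifih1 at -1.05 and Mx1 at 0.72, and passed without WT replicate 1 (0.20, camera adjusted p = 0.0318). Apoptosis genes shifted by 0.07 (0.036 to 0.11, camera adjusted p = 0.231), and Pmaip1 passed adjusted over the list alone. Glycolysis genes shifted by 0.03 (-0.14 to 0.14, camera adjusted p = 0.643), with Pkm at 0.19 (0.069 to 0.32) and Pfkfb3 at 0.28 (0.019 to 0.55). Heat shock and stress genes shifted by 0.16 (-0.26 to 0.44, camera adjusted p = 0.915), with Hspe1 at -0.28 (-0.37 to -0.18) and Hspd1 at -0.66 (-1.09 to -0.31). KO replicate 1 had a list score of 0.93, against -0.46 to 0.16 on the other arrays, and without it the shift turned to -0.26. Genes near Mir155 shifted by -0.05 (-0.087 to -0.023, camera adjusted p = 0.527), with Mrpl39, the next protein-coding gene beyond Mir155 in RefSeq of assembly GRCm38.p6, at -0.66 ± 0.19 (SE) and Bach1 at 0.74 (0.49 to 0.91).

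No marker list of a cell type passed. CD4 T cell markers shifted by 0.10 (0.042 to 0.17, camera adjusted p = 0.19), with Zbtb7b at 0.48 (0.29 to 0.60) and Cd2 at 0.28 (0.17 to 0.42), and CD8 markers had a mean of -0.01 (-0.15 to 0.11) and a median of 0.02 (camera adjusted p = 0.915), with Crtam at -0.49 (-0.70 to -0.23) and Runx3 at 0.54 (0.097 to 0.89). Without KO replicate 1 Crtam was at -0.23 and Runx3 at 0.097. B cell markers shifted by 0.02 (-0.22 to 0.21, camera adjusted p = 0.657), with Vpreb3 at 0.42 (0.23 to 0.59) and Ms4a1 at -0.70 (-1.22 to -0.39), macrophage and monocyte markers by 0.19 (0.11 to 0.25, camera adjusted p = 0.133), with Fcgr3 at 0.43 (0.25 to 0.63) and Cd68 at 0.63 (0.39 to 0.96), dendritic cell markers by 0.05 (-0.055 to 0.12, camera adjusted p = 0.675), with Bst2 at -0.56 (-0.87 to -0.39) and Flt3 at 0.17 (0.088 to 0.25), and platelet markers by 0.13 (0.084 to 0.16, camera adjusted p = 0.19), with Gp1bb at 0.18 (0.11 to 0.22) and Itgb3 at 0.23 (0.086 to 0.38). Markers of NK, gamma delta T, neutrophil and erythroid cells had 1, 2, 2 and 2 tested members and were not tested as lists, and these members differed by -0.25 (Blk, and -0.057 without WT replicate 1) to 0.49 (Cxcr2). Sex-linked genes shifted by 0.12 (-0.62 to 0.86, camera adjusted p = 0.874), with Uty at 0.16 (-0.33 to 0.85) and Kdm5d at 0.22 (-1.26 to 1.60), and their values varied widely within each genotype.

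**Figure D4:**
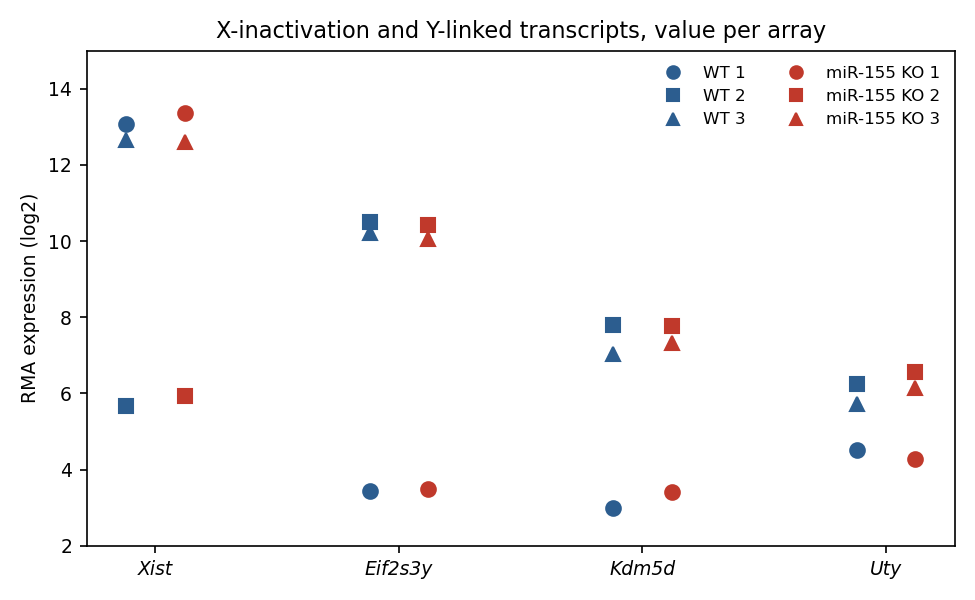
RMA expression (log2) of Xist and the Y-linked genes Eif2s3y, Kdm5d and Uty per array, for WT (blue) and miR-155 KO (red), with circles, squares and triangles for replicates 1, 2 and 3. Replicate 1 of both genotypes is bright for Xist, replicate 2 for the Y-linked genes and replicate 3 for both.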

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

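Leaving out the genes of chromosomes X and Y, which left 0 genes and 8 lists past, and leaving 6 members out of the target list (0.24, camera adjusted p = 0.00202) were chosen after seeing the data. Direction and side of the threshold held for the targeted gene under 13 of 14 alternatives, leave-one-out values running from -4.00 to -3.19. The 50% filter removed it. The count of 0 genes past limma's adjusted p under 0.05 moved under array weights alone, to 3581 (1662 higher, 1919 lower). There the unadjusted count was 4712, Mir155hg was at -2.45 (adjusted p = 0.0107, against 0.0107 to 0.880 over its alternatives) and 3 lists passed, the targets, cell cycle and type II interferon. By construction these weights let KO replicate 3 (5.55) and WT replicate 2 (5.05) outweigh the others (0.27 to 0.58). Leaving out 1 array, with 2 left in its group, gave 0 genes each time, 276 to 1540 genes unadjusted (458 without KO replicate 1, 1540 without KO replicate 2, 293 without KO replicate 3, 276, 280 and 1338 without WT replicates 1, 2 and 3) and 3 to 10 lists, the 3 without KO replicate 1. With an estimated correlation 0 lists passed adjusted and 1 unadjusted, and with fry 0 and 4. The target shift of 0.30 passed under neither (adjusted p = 0.528 and 0.218). It held in 16 of 18 alternatives, all at the preset correlation (0.23 to 0.35 with an array left out). Cell cycle held in 15 of 17, NF-kappa B and cytokine regulators in 13 and sterol synthesis in 12. Th17 and immediate early genes held in 11 and cytotoxic genes in 8, all at that correlation too. The cytotoxic call was lost under a further quantile normalization (adjusted p = 0.0612), no filter (0.072) and the 50% filter (0.126). Lists not past with all arrays passed in 12 values, 4 for Th2 (among them the 50% filter, 0.54, camera adjusted p = 0.00697), 3 for HIF response, 3 for type II interferon and 1 each for type I interferon and chemokines. With the replicate number as a block, limma gave 0 adjusted and 918 unadjusted genes and 7 lists, Th17 being lost (camera adjusted p = 0.0661). Deviations from the group means correlated, across genes, at -0.04, 0.64 and 0.40 for the pairs with numbers 1, 2 and 3. Across genotypes, replicates 2 and 3 correlated best with their own number. KO replicate 1 did so with WT replicate 3 (0.39) and WT replicate 1 with KO replicate 2 (0.32). The labels name no pairs, so the main test left the numbers unpaired, but a pairing by number is not excluded. Their sex markers match across genotypes, so the block also stands for these. Array weights turned Pfkfb3 (-0.38), Kdm5d (-0.093) and the lists of T cell activation (0.025), type I interferon (-0.13), glycolysis (-0.20), heat shock (-0.25), B cells (-0.31) and dendritic cells (-0.072). The 50% filter turned Th1 (-0.045), type I interferon (-0.000959), heat shock (-0.047) and B cells (-0.12), and no filter turned CD8 markers (0.012). None of these was past a test, and the cause was not tested. Single named genes kept direction and side in 899 values, passed in 57, all with array weights, and turned in 8. With an array left out, 29 of the 67 moved by over 1.5 times or turned, 0 of them among the 12 with the smallest p. With an array left out, signs also turned for Uty (-0.33 to 0.85), Kdm5d (-1.26 to 1.60) and the lists of type I interferon (-0.16 to 0.20), glycolysis (-0.14 to 0.14), HIF response (-0.15 to 0.78), heat shock (-0.26 to 0.44), sex-linked genes (-0.62 to 0.86), CD8 (-0.15 to 0.11), B cell (-0.22 to 0.21) and dendritic cell markers (-0.055 to 0.12). Dim genes limit what can be seen, since their differences are compressed. The planned seed match test and its alternatives were not run.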

Other observations

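Some further cytokine and ligand genes are given as values. They were chosen after their values were seen, no list of them was tested, and none passed the test over all genes. The tests of sex markers, of the animal's sex for the heat shock genes and of KO replicate 1 for the target list were chosen only after the result was seen. The lymphotoxin gene Lta measured 8.05 ± 0.58 in KO and 9.75 ± 0.70 in WT (SD, n = 3), a log2 difference of -1.70, with all KO arrays below all WT arrays. Il2, the growth factor of activated T cells, differed by -1.82 ± 0.71 (SE), Tnfsf11 by -1.57, Ifng by -1.17, Il3 by -0.94 and Tnf by -0.57. WT replicate 1 was the brightest array for each of these, with Il2 at 10.1 against 8.38 and 7.69 on the other WT arrays, and without it Il2 was at -1.12 and Il3 at -0.53. Il3 had a KO mean of 4.59, below that of the dimmest gene tested (4.72). Il13 and Il5, whose KO and WT arrays overlapped, were at 0.84 and 0.88, at 0.47 and 0.49 without KO replicate 1 and at 0.47 and 0.43 without WT replicate 2. Il21, close to Il2 in RefSeq of assembly GRCm38.p6, was at 2.24.

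Replicate 3 of both genotypes held Xist and Y-linked transcripts together, although the series description assigns 1 mouse to each array. Xist, the RNA of the inactive X, was at 12.6 on both replicate 3 arrays, 13.4 and 13.1 on replicate 1 and 5.94 and 5.66 on replicate 2 of KO and WT, while Eif2s3y was at 10.0 and 10.2 on replicate 3, 10.4 and 10.5 on replicate 2 and 3.50 and 3.44 on replicate 1. Probe background is argued against by a gap of 6.55 log2 units in Eif2s3y between the lower replicate 3 array and the higher replicate 1 array. In 8 of 8 comparisons replicate 3 lay above the array lacking the transcript, but this count restates the observation and cannot decide whether RNA of both sexes was present. That and an animal that itself makes both kinds of transcript stay open, and no biological explanation was tested.

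The shifts of the target and cell cycle lists were set against an expression axis that both genotypes share. The other lists past camera were not set against it. The first component of the residuals held 60.5% of the residual variance, and its loadings correlated with the KO minus WT differences at -0.71 across genes, which are not independent replicates. For the targets 75.6% of the shift (59.7 to 95.2, 95% bootstrap over members) was left once the trend of this axis was removed. Without KO replicate 1, 78.4% (61.8 to 93.6) was left. On these arrays the values argue against the axis as the main cause and against KO replicate 1 alone. The bootstrap draws members with the arrays held fixed, so its intervals do not measure the spread between mice. For cell cycle genes 43.6% (36.3 to 50.8) and 49.7% (43.7 to 56.0) were left, intervals that span 50%, so neither could be told apart from a difference of genotype. An effect of miR-155 loss on its reported targets remains a hypothesis, as lists chosen from these arrays and other differences between the mice were not excluded.

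KO replicate 1 had 10 genes over 2 log2 units above all other arrays. The heat shock genes Hspa1a and Hspa1b were at 9.72 and 10.3 there, Hspa1a being at 4.12 to 4.94 elsewhere, the hypoxia-responsive gene Adm at 8.89 and the metallothionein gene Mt2 at 12.6. RNA degradation is argued against, as the 3' minus 5' difference exceeded the other arrays in 0 of 2 control genes. The sex of the animal is argued against by Hspa1a in WT replicate 1, with the same sex markers, at -0.073 relative to the mean of replicates 2 and 3. Stress of that culture or animal may remain, and it was not tested.

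The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. As many genes past limma's adjusted threshold as with the genotypes (0) came from 10 of 10 splits, the highest other giving 875. As many at an unadjusted p under 0.05 (691) came from 2 of 10, the highest other giving 2810. As many lists (8) came from 5 of 10, the highest other giving 9. The number of lists past camera was thus not particular to the genotypes. As large a target shift (0.30) came from 1 of 10, the genotypes themselves, the highest other giving 0.22. The unadjusted camera p of the targets was 3.38e-07 there. With WT replicate 2 it was also 1.20e-05 beside KO replicates 1 and 2 and 0.000199 beside KO replicates 1 and 3. With WT replicate 3 these values were 0.000338 and 0.0340. Other splits gave up to 0.368. A small camera p for the targets was thus not particular to the genotypes. The split with 875 genes, KO replicates 1 and 3 with WT replicate 3 against the rest, follows the first principal component. That component was computed from the same arrays. The count thus restates the main structure of the samples, which did not separate the genotypes, and is not separate evidence for that structure.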
